A study of Homo sapiens with 2 samples.

How the data were processed

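Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on primary human aortic valve endothelial cells, the cells that line the valve leaflet. The cells had received a lentivirus carrying the NOTCH1 intracellular domain (NICD), the part of the receptor that is released on signalling and enters the nucleus, joined to a myc tag. Per the labels' protocols, they were fixed 48 to 72 hours after infection, chromatin bound by the tagged protein was recovered with an antibody against the tag, and repeated immunoprecipitations were pooled before a single library was made. The series thus held 2 libraries, 1 of immunoprecipitated DNA and 1 of input DNA, with no replicate of either.

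The deposited file was 1 list of sites for the pair of libraries. Per the file header, it gave for each site a chromosome, a single position with no width, a score and a smoothed enrichment. Per the submitters' processing notes, Bowtie was used and the genome build was hg19; the version of Bowtie, the program that called the sites, its settings and its threshold are not given in the sources used here. The score is the authors' own, sorted from high to low in the deposited list, and its scale is not stated. The enrichment was read as a linear ratio (fold) because the deposited values were all above 0 and exceeded 100, which values on a log2 scale would not; what it is relative to is not stated in the header. Scores and enrichments were used only to describe, rank and filter sites within this list. Read depth was not analysed here, so no interval that needs the number of reads is given.

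No genome sequence or gene annotation of hg19 was used here. The gene table at hand belonged to another build, GRCh38, and coordinates were not converted between builds. Comparisons planned before the data were examined that need gene positions or sequence were therefore not run. They were the share of sites near gene starts, 13 lists of genes (Notch targets, Notch pathway, calcification, shear response, endothelial identity, other cell types and others), the motif of the DNA-binding partner RBPJ, site strength by distance to a gene start, and sites in the NOTCH1 coding exons. The rule for named genes, also set beforehand, had further parts that need gene positions; what remained of it was the 15 sites of highest score, which are described by position. Those positions are as deposited, in hg19.

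What was computed from the list was the number of sites, their scores and enrichments, their density per autosome, their spacing, the 1 Mb windows holding most sites, and the relation of score to enrichment. Density was the number of sites divided by the distance from the first to the last site of the autosome, with an exact 95% Poisson interval that covers counting error only and takes sites as independent, which their spacing below does not bear out. Sex chromosomes were not described separately, since the cells came from a human donor. Spacing was compared with 1000 random placements that kept the number of sites per chromosome and drew positions evenly between its first and last site, leaving out its largest empty interval. The ratio of the densest to the sparsest autosome was set beside 10000 random sets in which the autosomal sites fell evenly over all spans. The 1-sided permutation p of the spacing has a smallest possible value of 0.001. The difference in median enrichment between score ranks was tested with 2-sided permutation tests of 100000 resamples. Rank correlations, and the difference in second numbers in the closing section, had 10000, so that their smallest possible p is 0.0001. In these tests the unit is the site or, for the likeness of neighbouring sites, the adjacent pair. A p-value thus describes this list and says nothing of another immunoprecipitation. The listing of sites by enrichment and the analysis of spacing, windows and score against enrichment was chosen after the list was seen. For density, the plan without chromosome lengths was the share of sites per chromosome with no test. Density over spans and the comparison of its ratio with random sets went beyond that plan.

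The calculations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9. They were tested on simulated data: of 20 sets of 8494 randomly placed sites, 1 was called closer than random at p of 0.05 or less, and all 20 sets in which about 10 percent of sites were moved to 5 kb from another site were called. Alternatives were the upper 4247 of the sites by score, merging of sites closer than 1 kb, other distances, other windows and other numbers of top sites.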

Results

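The data comprised 1 ChIP-seq library of chromatin recovered through the myc tag of the NOTCH1 intracellular domain, and 1 input library, both from infected primary human aortic valve endothelial cells. The study's title names calcification-related genes under shear stress and NOTCH1 as its subject, and this series asked where in the genome the tagged NICD was found. NICD does not bind DNA by itself; it is brought to DNA by the transcription factor RBPJ. With 1 library of each kind there was no replicate, and none of the values below has an error between replicates.

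The list deposited for the immunoprecipitated and input libraries held 8494 sites. Their median enrichment was 4.75-fold, with quartiles of 3.06-fold and 8.54-fold, and the highest was 109-fold. Enrichment was 10-fold or more at 1710 sites (20.1% of the list) and 20-fold or more at 616 sites (7.25%). At the low end, 689 sites (8.11%) had an enrichment under 2-fold. Of these, 81 sites were listed with an enrichment under 1. Their median score was 11.6 and their highest 49.4. The score had a floor of 10.3, a median of 13.1 and a maximum of 405. Most sites therefore had scores near the floor, with an upper quartile of 16.9, while 79 sites (0.930%) scored 50 or more and 16 sites scored 100 or more.

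The sites of highest enrichment were spread over many chromosomes. Among the 15 highest, 4 lay on chromosome 1, 2 on chromosome 3, 2 on chromosome 6, and 1 each on chromosomes 7, 10, 11, 12, 14, 17 and 18. The first was at position 19836729 of chromosome 12, with an enrichment of 109-fold and a score of 44.1. On chromosome 1, position 147266877 had an enrichment of 107-fold, position 55894943 of 97.8-fold, position 59349262 of 88.3-fold and position 179679237 of 69.3-fold. On chromosome 3, position 43431382 had an enrichment of 90.2-fold and position 193859241 of 73.1-fold. Chromosome 6 held a site of 82.6-fold at position 32164260 and a site of 76.9-fold at position 143141367. On chromosome 17 the site at position 18965571 was enriched 88.3-fold. The site at position 100781869 of chromosome 7 was enriched 71.2-fold and had another listed site 572 bp away. These highest values may rest on a constant added to low counts, a reading set out in the closing section, so their size is uncertain.

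The 15 sites of highest score were other sites, and 13 of them had an enrichment under 10-fold. The highest score, 405, was at position 44070724 of chromosome 9, where the enrichment was 2.42-fold. It ranked 7293 of 8494 by enrichment. A second site of that chromosome, at position 42416061, had a score of 186 and an enrichment of 2.28-fold. Chromosome 10 held 4 of the 15 highest scores, at positions 39149110 and 39153007 and at positions 42791299 and 42797293. Their scores were 196, 113, 105 and 108, and their enrichments 4.0-fold, 4.28-fold, 5.97-fold and 6.38-fold. Chromosome 11 held 3 of the 15. Of them, position 55026424 scored 178 with an enrichment of 3.54-fold, position 85195047 scored 157 with 4.36-fold, and position 62609157 scored 131 with 10.8-fold. On chromosome 3, position 196625741 scored 180 with an enrichment of 3.91-fold and position 90447948 scored 137 with 7.71-fold. The site at position 10764687 of chromosome 19 had the highest enrichment of the 15, 22.5-fold, with a score of 118. The lowest enrichment of the 15 was 1.38-fold, at position 119558565 of chromosome 6, where the score was 110. The remaining 2 sites lay on chromosome 14 at position 19019129, with 2.76-fold, and on chromosome 12 at position 38038126, with 2.35-fold.

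Across all sites, score and enrichment were weakly related. The Spearman rank correlation was 0.26 over 8494 sites (permutation p = 0.0001, the smallest that 10000 permutations can give). Sites are not independent replicates. Both values describe the same sites in the same pair of libraries, so they may be related by construction. The p-value therefore carries little weight. Only 1 site was among both the 100 highest scores and the 102 sites, ties included, of the 100 highest enrichments, where independent ranks would give 1.2. Median enrichment was 3.93-fold in ranks 6001 to 8494 by score and 8.27-fold in ranks 51 to 500. In the 50 highest scores it was 4.30-fold, a difference of -3.98 from ranks 51 to 500 on the fold scale (2-sided permutation test, p = 0.0007). For the 100 highest scores the difference was smaller, at -1.81 (permutation p = 0.017). Within the 500 highest scores the correlation was -0.066 (permutation p = 0.1).

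**Figure D1:**
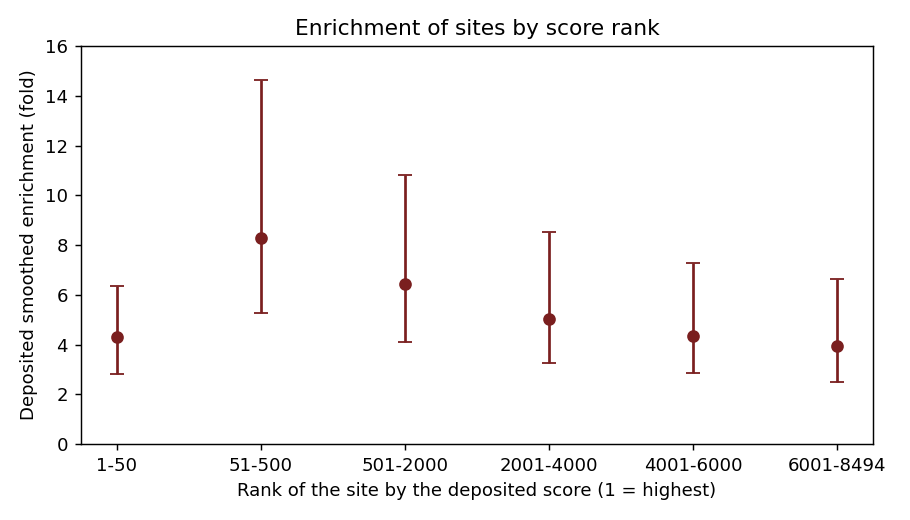
Deposited smoothed enrichment (fold, vertical axis) of sites grouped by their rank in the deposited score (horizontal axis, rank 1 highest); points are medians and bars run from the lower to the upper quartile over sites. The median falls from 8.27-fold in ranks 51 to 500 to 3.93-fold in ranks 6001 to 8494, and the 50 highest scores stand at 4.30-fold.

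Every autosome held sites, at densities that differed by about a factor of 1.95 between the extremes. Chromosome 19 was the densest, with 254 sites or 4.33 per Mb (95% interval 3.81 to 4.90). Chromosome 17 followed with 326 sites or 4.03 per Mb (3.60 to 4.49), then chromosome 21 with 3.95 per Mb (3.35 to 4.63). Of the 152 sites on chromosome 21, 30 lay in a single window, at 10 to 11 Mb. Its high place thus rests in part on that window, and its density without the window was not computed. The sparsest were chromosome 4, with 424 sites or 2.22 per Mb (2.02 to 2.44), chromosome 13 with 2.24 per Mb (1.95 to 2.56) and chromosome 18 with 2.34 per Mb (2.02 to 2.71). The ratio of the densest to the sparsest autosome, 1.95, exceeds 1 by the choice of the extremes. In 10000 random sets with sites spread evenly over all autosomal spans, this ratio had a mean of 1.27 and a highest value of 1.92. After sites closer than 1 kb were merged it was 1.93, which 1 of 10000 such sets reached. After merging within 10 kb it was 1.88, for chromosome 19 over chromosome 13, and none of the 10000 sets reached it, with a highest value of 1.80. Such sets take sites as independent, which their spacing below does not bear out, so the range they give is likely too narrow. The densities are a description: copy number, gene density and mapping can all act on them and were not examined. Median enrichment ranged less, from 3.94-fold on chromosome 21 to 5.51-fold on chromosome 22. Chromosome 1 had the most sites, 836, at 3.37 per Mb (3.14 to 3.60).

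**Figure D2:**
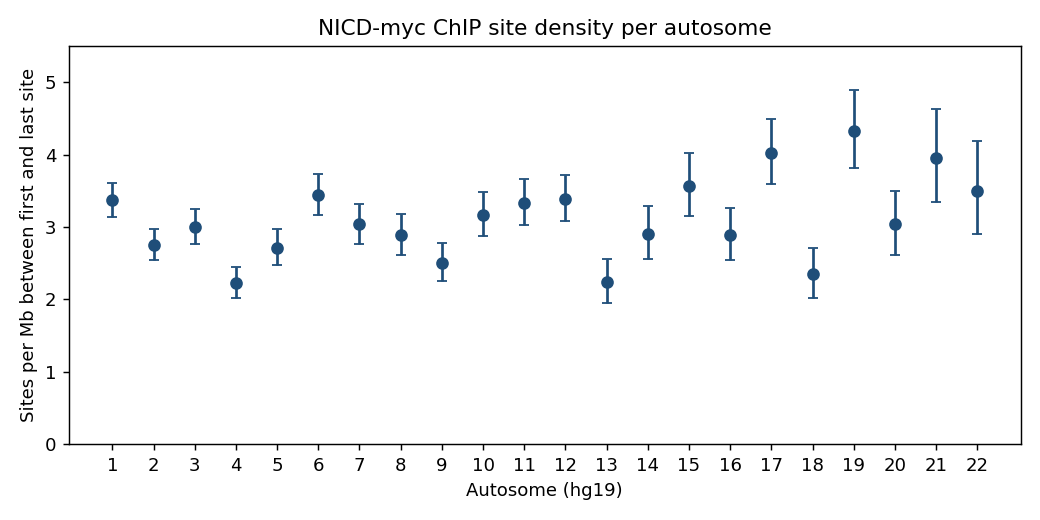
Sites per Mb between the first and the last site (vertical axis) for each of the 22 autosomes in hg19 (horizontal axis); points are densities and bars are exact 95% Poisson intervals, which cover counting error only. Chromosomes 19, 17 and 21 stand highest, at 4.33, 4.03 and 3.95 per Mb, and chromosomes 4, 13 and 18 lowest, at 2.22, 2.24 and 2.34 per Mb. Of the 152 sites on chromosome 21, 30 lay at 10 to 11 Mb.

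Sites lay closer together than random positions did. Another site lay within 10 kb of 25.6% of sites, against a mean of 6.23% and a highest value of 7.25% in 1000 random placements (1-sided permutation p = 0.001, the smallest these placements can give). Adjacent sites less than 1 kb apart numbered 368 pairs, 13.5 times the random mean of 27.2. The excess fell with distance, to 7.93 times at 1 to 2 kb, 4.21 times at 2 to 5 kb, 2.89 times at 5 to 10 kb and 1.41 times at 20 to 50 kb. At 50 to 100 kb the 1027 observed pairs lay within the range of the placements, 965 to 1177. No sites were closer than 197 bp. The median distance to the nearest site was 45.2 kb.

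**Figure D3:**
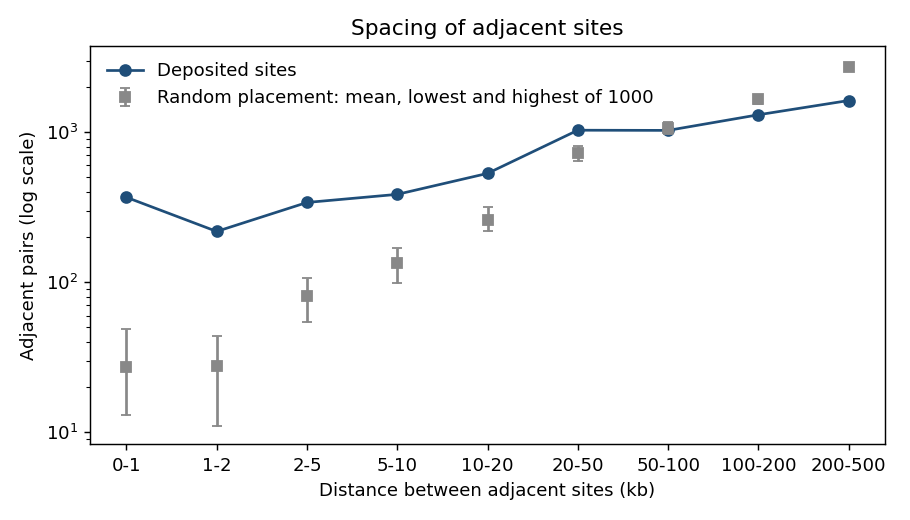
Number of pairs of adjacent sites (vertical axis, log scale) by the distance between them in kb (horizontal axis); circles are the deposited sites, squares the mean of 1000 random placements, and bars their lowest and highest values. Deposited pairs exceed every placement up to 50 kb, with 368 against a random mean of 27.2 below 1 kb, and meet the random range at 50 to 100 kb.

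Sites were also crowded at the scale of 1 Mb. Of the autosomal windows of 1 Mb with any site, the median number was 3, and 112 windows held 10 or more. In 14 windows the number exceeded 16, the largest in any window of any of the 1000 random placements. Once sites closer than 1 kb were merged, only 5 windows exceeded the largest of their own placements, 17. They were the windows described next on chromosomes 15, 21, 17 and 11, and the window at 145 to 146 Mb of chromosome 1. The most crowded window was at 39 to 40 Mb of chromosome 15, where 41 sites lay between positions 39119255 and 39917190. Their median enrichment was 4.53-fold and the highest 42.7-fold; counted as chains of sites closer than 1 kb, they came to 19. After such merging the most crowded window was at 10 to 11 Mb of chromosome 21, with 24 sites, and with windows shifted by 0.5 Mb it was also on chromosome 21, with 40. On chromosome 17, 29 sites lay between positions 57232541 and 57933218, with a median of 5.56-fold, and 21 remained after merging. Chromosome 11 had 24 sites between 65042898 and 65769624 (median 5.51-fold), of which 20 remained. Other windows did not exceed the placements once merged. On chromosome 5, 22 sites between 172142130 and 172571530 (median 5.23-fold) came to 12. On chromosome 7, 21 sites between 100026909 and 100783067 (median 6.64-fold, highest 71.2-fold) also came to 12. In the window at 59 to 60 Mb of chromosome 1, 19 sites had a median of 5.51-fold, the highest was 88.3-fold, and 15 remained.

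A few crowded windows had low enrichment. On chromosome 21, 30 sites between positions 10085062 and 10852724 had a median of 3.01-fold and none above 7.91-fold; 24 remained after merging. On chromosome 10, 26 sites lay within positions 39081525 to 39154889, with a median of 3.52-fold but a median score of 29.9, against 13.1 in the whole list; these came to 15. On chromosome 1, 19 sites between 145039665 and 145723679 had a median of 2.85-fold, and all 19 remained. These windows, like all positions above, are given without gene annotation, and which genes they hold was not analysed here.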

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

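The alternatives for spacing, score against enrichment and crowded windows were chosen after the list was seen, as were the shorter span and the merging within 10 kb for density. The stronger sites by score, taken up to the median, numbered 4247 by construction, and merging sites closer than 1 kb left 8126. The density ratio between the densest and the sparsest autosome stayed close to the 1.95 of the whole list, at 2.12 in the stronger sites (where chromosome 17 replaced chromosome 19), 1.93 after merging, 1.88 after merging within 10 kb and 2.02 without each chromosome's largest empty interval. The share of sites with a close neighbour stayed above every random placement in all 8 alternatives run, which included distances of 1 kb and 100 kb. Within 10 kb it was 20.3% after merging against 5.96% at random. It was 16.2% in the 4247 sites of highest enrichment against 3.28%, and 19.7% without the windows of 10 or more sites against 5.11%. The correlation of score with enrichment was 0.26 after merging and without the 50 highest scores and 0.21 in the stronger sites, but turned to -0.066 within the 500 highest scores, where the 50 highest had the lower enrichment. That difference of medians was -3.92 for the 20 highest scores (2-sided permutation p = 0.025), -1.81 for the 100 highest (p = 0.017) and -3.88 after merging. The most crowded window fell from 41 to 24 sites after merging and was then on chromosome 21, at 10 to 11 Mb, because the sites on chromosome 15 form chains; with windows shifted by 0.5 Mb it was on chromosome 21 with 40 sites, and in the stronger sites on chromosome 15 with 29. Windows above every random placement numbered 14 as deposited, 5 after merging and 13 with shifted windows. Alternatives that need gene positions, chromosome lengths or sequence of hg19 were not run, nor were sex chromosomes left out, since they were not described separately. With 1 library per group, no replicate could be left out, and no paired analysis was possible because each group had 1 library.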

Other observations

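Of the tests below, those on the grid of enrichment values and on pairs of sites 5 to 10 kb apart were chosen after their results had been seen, and the test of second numbers in the 50 highest scores was changed to matched enrichment after an unmatched form of it had been seen; the rest were set out before their results were known. Neighbouring sites were of somewhat like strength. Between adjacent sites 1 to 10 kb apart the Spearman correlation of enrichment was 0.13 over 943 pairs (permutation p = 0.0001). The permutation takes pairs as independent, but pairs in a chain share sites, so this p-value is likely too small. It was 0.10 below 1 kb (368 pairs, permutation p = 0.06), 0.03 at 10 to 100 kb (2588 pairs, p = 0.09) and 0.02 at 100 to 1000 kb (3853 pairs, p = 0.2). The 4 distances are 1 family, and whether they differ from each other was not tested. Signal shared over a stretch of chromatin is a hypothesis that the value at 1 to 10 kb goes with, though 0.13 leaves most of the ranking of neighbours unrelated. The value below 1 kb was not higher and does not add to it. Overlap of the authors' smoothing windows stays open.

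The 8494 enrichment values took only 500 distinct levels, with 351 sites at 2.85-fold, 319 at 4.75-fold, 236 at 6.64-fold and 180 at 8.54-fold. A candidate explanation is that each value is a factor times the ratio of 2 whole numbers with 0.5 added to each. With a factor of 0.949, found from the commonest value as the one that gives the smallest whole numbers, 99.3% of values were met to a relative tolerance of 1e-08 with a second number of at most 20, and 100% with at most 300. After rescaling all values by 3 other factors, 0% and at most 0.0706% were met. By arithmetic, these factors move any value of the grid off it. The low shares therefore show only how seldom values off the grid meet the tolerance. If the numbers are read counts of the ChIP and input libraries, which the header does not say, then the smallest pair behind the highest enrichment, 109-fold, is 57 against 0, and all 102 sites of the highest enrichments have a smallest second number of 0. Their fold would then rest on the added 0.5. In the whole list, 2334 sites (27.5%) had a smallest second number of 0. The pairs are the smallest possible, since any odd multiple gives the same ratio, so they cannot be taken as the counts themselves.

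This reading bears on the 50 highest scores, whose median enrichment of 4.30-fold was below the 8.27-fold of ranks 51 to 500. Sequence that gathers reads in both libraries, such as repeats that the reference holds in too few copies, would give many reads at a modest ratio. Among sites with an enrichment between 2.83-fold and 6.37-fold, the smallest second number had a median of 24.5 in the 24 sites of the top 50 and of 2 in the 3715 later sites, a difference of 22.5 (2-sided permutation p = 0.0001, the smallest possible). This does not decide the matter: the score rose with the smallest first number (Spearman 0.42 across the sites of that range), so at a like ratio a higher score brings a larger second number whatever the source. The explanation cannot be told apart from others by these numbers. The site of highest score was the last before the largest empty interval of chromosome 9, which spanned 22.7 Mb. The nearest site to it, 1654663 bp away, was that of score 186 at position 42416061. On chromosome 3, the site of score 180 at position 196625741 was the last listed. On chromosome 14, position 19019129 lay near the first listed site, 19001241. The others on chromosomes 3, 6, 11, 12 and 19 among the 15 were neither first nor last nor beside the largest empty interval. The 4 sites of chromosome 10 among the 15 highest scores did not border that chromosome's largest empty interval, at 55163529 to 59783793. Whether they bordered a smaller empty interval was not examined, so this is no evidence against repeated sequence there. Whether the highest scores lie by empty intervals or chromosome ends more than other sites do was not tested. In the top 50, 43 sites had a second number of 5 or more. The other 7 had a median enrichment of 15.6-fold. The 328 sites of ranks 51 to 500 with a second number below 5 had 10.4-fold, a difference that was not tested. Over all sites the score rose with the smallest first number (Spearman 0.45). With the second number held low, a higher ratio in the top scores is therefore likely whatever the source. Of the top 50, 30 lay within 10 kb of another site, as did 167 of the 450 next sites. Whether NICD is bound at these sites as well stays open and was not tested.

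The closeness of sites has technical explanations that the list can address in part. If it came only from single peaks listed as several sites, the excess would end at the width of a peak, yet pairs 5 to 10 kb apart were 2.89 times as frequent as at random (385 against 133) and above every placement. Splitting of peaks less than 5 kb wide thus fails as the whole cause. The list gives no widths, so broader regions listed as several sites cannot be excluded, and splitting may add to the excess at shorter distances. For sequence that gathers reads in both libraries, leaving out sites with a smallest second number of 5 or more left 21.6% of the others with a neighbour within 10 kb, against 5.42% at random. About 186 sites of larger second number are expected to reduce to a smaller pair and so to remain, and even if each accounted for itself and both its neighbours, 14.3% would be left. Provided that the second number stands for input reads, sequence that gathers 5 or more of them thus fails as the whole cause. The median smallest second number of the list was 2. Sequence that gathers fewer than 5 input reads, yet more than its surroundings, stays in the set, so this cut cannot exclude it. Uneven mapping, open chromatin that is recovered by any antibody, and groups of true binding sites remain open, since no control immunoprecipitation and no annotation were analysed here.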
